A study of Mus musculus with 3 samples.

How the data were processed

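Total RNA of sinonasal mucosa was measured on 3 Illumina mouse bead arrays, each hybridised with biotin-labelled cRNA of a pool of 5 mice, 1 array for each of the groups control_WT, ECRS_WT and ECRS_KO. Groups were taken from the labels. The deposited non-normalized table holds for each of 35226 probes a signal intensity and a detection p-value, per the file headers. The series table holds normalized intensity made by the authors on a linear scale. BeadStudio is credited by the submitters' processing notes, without a version, and the genome build and annotation release are not given in the sources used here. On the array labelled control_WT the authors' values equalled the non-normalized signal plus a constant of 70.6. The medians of the authors' values were 77.5, 76.8 and 76.7 on the arrays labelled control_WT, ECRS_WT and ECRS_KO.

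The values used here were computed from the non-normalized table with limma 3.58.1 in R 4.3.3. Background was corrected by the normexp method with an offset of 16, arrays were quantile normalized together, and signals were put on the log2 scale. The mean and SD of negative controls were inferred from the detection p-values. The design fixed before the data were examined was limma's neqc procedure with its own inference. That inference takes the detection p-value to fall with the signal in every probe, which was not so here: 153, 178 and 222 probes with a signal over 1000 were not detected on the arrays labelled control_WT, ECRS_WT and ECRS_KO. It gave SDs of 259.6, 356 and 361. The median signal in 100 bins of the detection p-value was used in its place and gave SDs of 9.23, 13.7 and 16.9. This departure from the design was made after values, including those of Scgb1a1, had been seen, and it raised the number of genes called; counts under limma's own inference are printed beside those reported, with its values for Scgb1a1, and, in the 2 main comparisons, for the lists outside percentiles 2.5 to 97.5 and those whose median it moved by more than 0.2, a bound chosen after the values were seen.

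A probe was detected at a detection p-value under 0.01. A gene was measured in a comparison when its probe was detected on either array. It was called higher or lower at 2-fold or more when its probe was detected on the brighter array. Where the probe was not detected on the dimmer array, its level there was taken as the higher of its own value and the lowest level of any detected probe on that array, and the fold is printed as a lower bound. Such a bound holds only under the background inference used here, and other settings can give a smaller fold. These lowest levels were 5.19, 5.06 and 5.00 on the log2 scale. Of the probes, 20571 had 1 gene symbol, 10 had several and 14645 had none; the latter 2 kinds were not used for genes. The named probes stood for 17349 genes, 2558 of them with 2 or more probes, of which the probe with the highest mean signal was used. Entrez identifiers matched 20525 named probes to the RefSeq gene table of assembly GRCm38.p6, used only for names and gene order.

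With 1 array per group no gene or list has a p-value or a replicate error. The bootstrap SDs printed are over the members of a list, and the Fisher exact test counts genes on a chromosome; neither measures variation between mice. The genes named were fixed by rule: Scgb1a1, the 10 highest and 10 lowest genes detected on both arrays, the 3 highest and 3 lowest detected on 1 array only, and of each list the 3 largest members at 2-fold or more, or otherwise the 2 with the highest mean signal. There were 136 such genes. In all, 35 lists with 473 entries, 408 of them with a probe, were written before the data were examined. The median of each list was placed among 10000 random lists of the same size drawn from 20 bins of signal, as a description of these arrays. Families of olfactory receptors, melanocyte genes and cytosolic ribosomal proteins were added after values were seen. The sharing of an array by both main comparisons was modelled by 100 simulated sets of arrays without differences. Alternatives planned before numbered 10 and those added after seeing the data 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

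The procedure was tested on simulated data for the comparison of ECRS_WT with control_WT, with 35226 probes and 50 changed probes at each fold. At 1.5-fold 4 of 50 were called, at 2-fold 17, at 3-fold 48 and at 4-fold 43. Median recovered folds were 1.47, 1.84, 2.88 and 3.46, and 22 of 18023 unchanged detected probes were called. The simulated noise was a chosen value, and changed probes were taken from those detected on all arrays above a set signal. Detection p-values followed the simulated signal, so bright probes that are not detected were absent. The 22 calls therefore give no error rate for these arrays. Probes of the same gene differed by a pooled SD of 0.50 on the log2 scale over 370 genes in the disease comparison and 0.29 over 491 genes in the genotype comparison.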

Results

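Gene expression was measured in the sinonasal mucosa, the lining of the nose and paranasal sinuses, of C57BL/6 mice of 6 to 8 weeks of age. There were 3 groups, namely wild-type mice without disease (control_WT), wild-type mice in which eosinophilic chronic rhinosinusitis of allergic type had been induced (ECRS_WT) and mice lacking CC10 with the same disease (ECRS_KO). CC10, the product of Scgb1a1, is the club cell secretory protein, an abundant secretoglobin of airway lining fluid. RNA of 5 mice was pooled for each group and hybridised to 1 Illumina bead array, so that 15 mice gave 3 arrays and no difference below has a replicate check. The number of arrays limits the precision of each value. The arrays differed in brightness: the mean signal was 295 on the array labelled control_WT, 373 on the array labelled ECRS_WT and 465 on the array labelled ECRS_KO. On these arrays 11428, 11992 and 12508 of 35226 probes were detected.

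The targeted gene was examined first. The signal of Scgb1a1 was 3.32 on the array labelled control_WT, where it was not detected, 493 on the array labelled ECRS_WT and 597 on the array labelled ECRS_KO. Scgb1a1 was thus at least 14.3-fold higher on the array labelled ECRS_WT than on the array labelled control_WT, and 1.14-fold lower on the array labelled ECRS_KO than on the array labelled ECRS_WT, a difference that changed sign under median scaling. Under limma's own inference of the background, the procedure fixed beforehand, the first of these differences was 0.86 on the log2 scale, below 2-fold. These values went against 2 of the 3 labels, since a wild-type pool lacked the signal and the knockout pool carried it. Only 1 probe of the gene was named, and its place relative to the deleted part of the gene is not known here. A probe outside that part could carry signal in the knockout pool and would not check the label ECRS_KO. The place of the probe does not bear on the lack of signal on the array labelled control_WT. Arrays are therefore named by their labels, and each direction below, disease or genotype, rests on labels that this gene did not bear out.

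**Figure D1:**
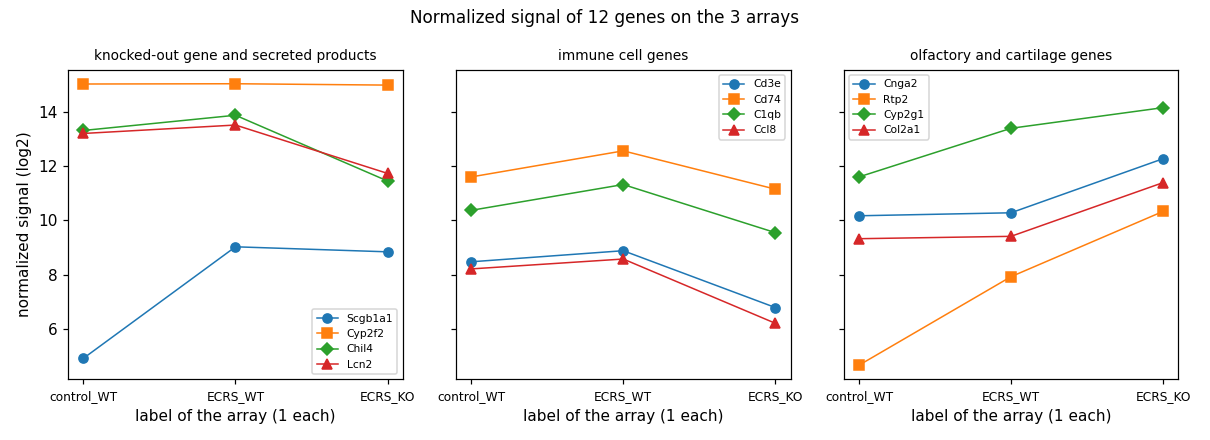
Normalized signal (vertical axis, log2) of 12 genes on the arrays labelled control_WT, ECRS_WT and ECRS_KO (horizontal axis), with 1 point per array and lines that only join the points of a gene. Scgb1a1 lay at 4.92, 9.03 and 8.84, while the immune cell genes were lowest and the olfactory and cartilage genes highest on the array labelled ECRS_KO.

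The comparison of ECRS_WT with control_WT asked how the mucosa of wild-type mice differed with the disease. On the array labelled ECRS_WT, the medians of macrophage genes, of immediate early and heat shock genes and of genes of the unfolded protein response were higher, though few members reached 2-fold, and 4 of 10 neutrophil genes were lower. Ms4a7, a macrophage membrane protein, was 2.85-fold higher, Herpud1, which serves the degradation of proteins at the endoplasmic reticulum, was 2.66-fold higher, and Fos, an immediate early transcription factor, was 2.39-fold higher. S100a9, a calcium-binding protein of neutrophils, was 2.61-fold lower and Camp, the antimicrobial cathelicidin peptide, was 2.52-fold lower. In all, 328 genes were at least 2-fold higher and 125 at least 2-fold lower among 8771 genes detected on either array, and 94.8% of these genes lay within 2-fold.

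Among genes detected on both arrays, the largest difference upward was that of Rnf13, a ubiquitin ligase of endosomal membranes, with signals of 45.7 on the array labelled control_WT and 1655 on the array labelled ECRS_WT (17.4-fold). Atp6ap2, the prorenin receptor and an accessory protein of the vacuolar proton pump, was 8.30-fold higher, and Atp6v1a, the catalytic subunit of that pump, 5.48-fold higher. Mmp3, the matrix protease stromelysin, was 8.28-fold higher. Gsn, which encodes the actin-severing protein gelsolin, was 7.93-fold higher, Snurf of an imprinted locus 7.30-fold and Serinc2 6.91-fold. Igfbp2, a binding protein of insulin-like growth factors, was 5.90-fold higher, the fibroblast growth factor receptor gene Fgfr3 5.24-fold, and Ugt2a1, a glucuronosyltransferase of the olfactory epithelium, 5.09-fold. Of genes not detected on the array labelled control_WT, BC018473 was at least 85.4-fold higher, and Rbbp7, a histone-binding protein of chromatin complexes, at least 14.4-fold higher. Second probes of these genes did not always follow: another probe of Snurf differed by -0.41 and another of Atp6v1a by -0.22 on the log2 scale, while that of BC018473 differed by 3.15.

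Among genes detected on both arrays, the largest difference downward was that of Fbxw5, an F-box protein of ubiquitin ligases, with signals of 1758 on the array labelled control_WT and 63.0 on the array labelled ECRS_WT (28.5-fold). Serpina1e, of the alpha-1-antitrypsin family, was 6.44-fold lower, the secretoglobin gene Scgb2b24 5.74-fold, and Rec8, a meiotic cohesin subunit, 4.54-fold. Atp6v1c2, a further subunit of the proton pump, was 3.55-fold lower, Pnliprp1, a relative of pancreatic lipase, 3.48-fold, and Itln1, the lectin intelectin, 3.37-fold. Slc4a1, the anion exchanger of red cells, was 3.23-fold lower, Gbf1, an exchange factor of the Golgi, 3.15-fold, and Ifitm6 2.92-fold. Genes detected on the array labelled control_WT and not on the array labelled ECRS_WT included Bpifb9b, a secreted protein of nasal glands, at least 47.4-fold lower on the array labelled ECRS_WT. Aldh1a7, an aldehyde dehydrogenase, was at least 5.05-fold lower there, and Pvalb, a calcium-binding protein of fast muscle, at least 4.84-fold lower.

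Of 8 measured macrophage and dendritic cell markers, 2 were at least 2-fold higher and none lower on the array labelled ECRS_WT, with a median log2 difference of 0.51 at percentile 99.9 of 10000 random lists matched for size and signal. C1qc, a complement component made by macrophages, was 2.36-fold higher. The 9 measured genes of MHC class II presentation all lay within 2-fold, with a median of 0.31 at percentile 99.2, and H2-Ab1 and H2-Eb1 were 1.80-fold and 1.15-fold higher. Of 10 measured neutrophil markers, 4 were at least 2-fold lower and none higher, with a median of -0.90 at percentile 0. Ctsg, the neutrophil protease cathepsin G, was 2.48-fold lower. The 3 measured eosinophil markers had a median of -0.85 at percentile 0.475 (-0.05 under limma's own inference); Prg2, the eosinophil major basic protein, had signals of 1307 on the array labelled control_WT and 886 on the array labelled ECRS_WT, 1.95-fold lower, and Il5ra was at least 1.46-fold lower. Of the 7 measured B cell and plasma cell markers 1 was lower, Cd79b of the B cell receptor by 2.01-fold, with a list median of -0.44 at percentile 4.66; under limma's own inference these were -0.35 (log2) for Cd79b and -0.03 for the list.

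Lists of type 2 inflammation did not stand apart on the array labelled ECRS_WT, in the members that were detected. Of 15 type 2, 14 mast cell and basophil and 12 T cell genes with a probe, 6, 4 and 4 were measured. Among 6 measured type 2 cytokines, receptors and factors, Stat6, the transcription factor downstream of interleukin-4 and interleukin-13, was at least 2.24-fold higher. Its difference was 0.09 (log2) under limma's own inference. The list median was 0.08 at percentile 77.2 (negative with the authors' values and without a detection filter). The 12 measured interleukin-13 responsive airway genes had a median of -0.12 at percentile 44.4, with Serpinb2 2.06-fold higher and Itln1 lower as given. All 6 measured chitinases and chitinase-like proteins lay within 2-fold at a median of 0.22 (percentile 92.9), and Chil4 and Chil1 were 1.47-fold and 1.41-fold higher. The 5 measured chemokines of eosinophil and Th2 cell recruitment had a median of 0.34 at percentile 95.2 (-0.09 without a detection filter), with Ccl8 1.29-fold and Ccl7 1.27-fold higher. Of 4 measured mast cell and basophil markers, the mast cell protease gene Mcpt4 was 2.45-fold higher, with a list median of 0.17 at percentile 87.4 that was negative without a detection filter. The 4 measured T cell markers had a median of 0.09 at percentile 76.2, with Cd3g 1.60-fold higher and Cd3d 1.17-fold lower.

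Stress and mediator lists were mixed on the array labelled ECRS_WT. Immediate early and heat shock genes had a median of 0.55 at percentile 99.9, 2 of 7 being at least 2-fold higher, and Hspa1a, an inducible heat shock protein, was at least 2.50-fold higher. The 8 measured genes of the unfolded protein response had a median of 0.55 at percentile 99.97, with 1, Herpud1, at least 2-fold higher and 3 below 0. Of 6 pro-inflammatory cytokines and mediators, Cxcl1, a neutrophil-attracting chemokine, was 2.59-fold higher, Saa3, an acute phase protein, at least 2.48-fold higher and Csf2 at least 2.28-fold lower, with a median of 0.16 at percentile 89.3. Under limma's own inference Cxcl1 differed by 0.92, Saa3 by 0.11 and Csf2 by -0.08 (log2). The median of 9 eicosanoid genes was 0.28 at percentile 97.3, with the prostaglandin D synthase gene Hpgds at least 2.0-fold higher; under limma's own inference these were 0.04 for the list and 0.06 (log2) for Hpgds. The 5 interferon response genes (median 0.11, percentile 79.5, negative with the authors' values) and the 6 NF-kB feedback and target genes (median 0.07, percentile 80.3, negative with the authors' values and with probes detected on all 3 arrays) all lay within 2-fold; Rsad2 was 1.02-fold and Sod2 1.03-fold lower, and Cxcl9 1.14-fold and Icam1 1.24-fold higher.

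Epithelial lists differed in both directions on the array labelled ECRS_WT. The 10 other club cell and surface secretory products all lay within 2-fold, with a median of -0.19 at percentile 11.4, and Cyp2f2 and Cbr2, enzymes abundant in club cells, differed 1.01-fold and 1.28-fold. The cell surface mucin gene Muc1 was 2.04-fold higher among 8 mucins and trefoil factors (median -0.15, percentile 27.6). Of 8 antimicrobial and innate defence proteins 1, Camp, was lower (median -0.12, percentile 33.6). Ciliated cell genes had a median of -0.33 at percentile 5.04, with Rsph1 1.20-fold and Tppp3 1.52-fold lower, and extracellular matrix genes one of -0.10 at percentile 38.2 (0.01 under median scaling), with Mmp2 1.07-fold and Ccn2 1.88-fold lower. Of 8 sustentacular cell and Bowman's gland markers of the olfactory mucosa 2 were higher, Ugt2a1 and the olfactory cytochrome Cyp2g1 (3.45-fold), with 3 members below 0 and a median of 0.37 at percentile 99.8, smaller than its bootstrap SD of 0.44. Of 14 olfactory sensory neuron markers, Rtp2, which carries odorant receptors to the membrane, was at least 6.66-fold higher, Stoml3 2.59-fold higher and Gng8 2.38-fold lower, with a median of 0.07 at percentile 90.2 that was negative after scaling on probes detected on all arrays and with probes detected on all 3 arrays.

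Further tissue lists had medians inside the range of most random lists in this comparison. Nasal gland secretory proteins had a median of 0.09 (percentile 87.1; negative under median scaling and after scaling on probes detected on all arrays), with Obp1a 2.14-fold and Pip 2.06-fold lower beside Bpifb9b. Squamous keratinocyte genes had a median of 0.08 at percentile 84.2, negative with the authors' values and with probes detected on all 3 arrays. Krt1 was at least 2.36-fold higher (0.09 log2 under limma's own inference). Bone and cartilage genes had a median of 0.08 at percentile 84.6, or -0.12 after scaling on probes detected on all arrays. Phex was 2.13-fold and Sp7 2.04-fold lower, although another probe of Sp7 differed by 0.29 (log2). Skeletal muscle genes had a median of 0.09 (percentile 79.2, negative without a detection filter), adipocyte genes -0.08 (percentile 52.8, positive under median scaling) with Cidea 1.05-fold and Adipoq 1.63-fold lower, erythroid genes -0.21 (percentile 21.1) and cell cycle genes -0.39 (percentile 8.87) with Mcm5 1.64-fold lower and Birc5 1.03-fold higher. Of 8 reference genes, Gusb was 2.73-fold higher, with another probe at 0.02 (log2), and the list median was -0.07 at percentile 39.2. Among 22 measured chromosome neighbours of Scgb1a1, Stx5a, a syntaxin of Golgi transport, was 2.37-fold higher, with a median of -0.04 at percentile 65.4 that was positive under median scaling and without a detection filter. None of the 4 sex-linked genes with a probe was detected. In families chosen after their values were seen, the median was -0.32 (percentile 0) for 196 measured olfactory receptor genes, of which 4 were higher and 2 lower (-0.02 under limma's own inference, with none higher or lower), and -0.17 (percentile 1.78) for 38 cytosolic ribosomal protein genes. Of 2 measured melanocyte genes 1 was higher, with a median of 0.96 at percentile 98.8 (0.87 under limma's own inference, and -0.05 without a detection filter).

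Counts of this comparison depended on scaling and background: median scaling gave 511 genes higher and 43 lower, so that 92.2% of the genes apart were higher against 72.4% under quantile normalization, and the median of all genes detected on both arrays was 0.10 against -0.09. With limma's own inference of the background the counts were 108 and 41, of which 70 and 15 genes were shared, and 20 of the 54 named genes at 2-fold or more kept that size. Of the genes named for the largest differences, Rnf13, Atp6ap2, Gsn, Igfbp2, Atp6v1a, Ugt2a1, BC018473, Rbbp7, Fbxw5, Slc4a1 and Bpifb9b kept 2-fold there, whereas Mmp3 (0.58 log2), Snurf (0.80), Serinc2 (0.61), Fgfr3 (0.38) and the other genes lower on the array labelled ECRS_WT did not. List medians there were 0.22 for macrophage, 0.22 for MHC class II, -0.58 for neutrophil, 0.39 for immediate early and heat shock, 0.39 for unfolded protein response, 0.39 for sustentacular, 0.05 for chemokine, -0.06 for ciliated cell and -0.08 for cell cycle genes.

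**Figure D2:**
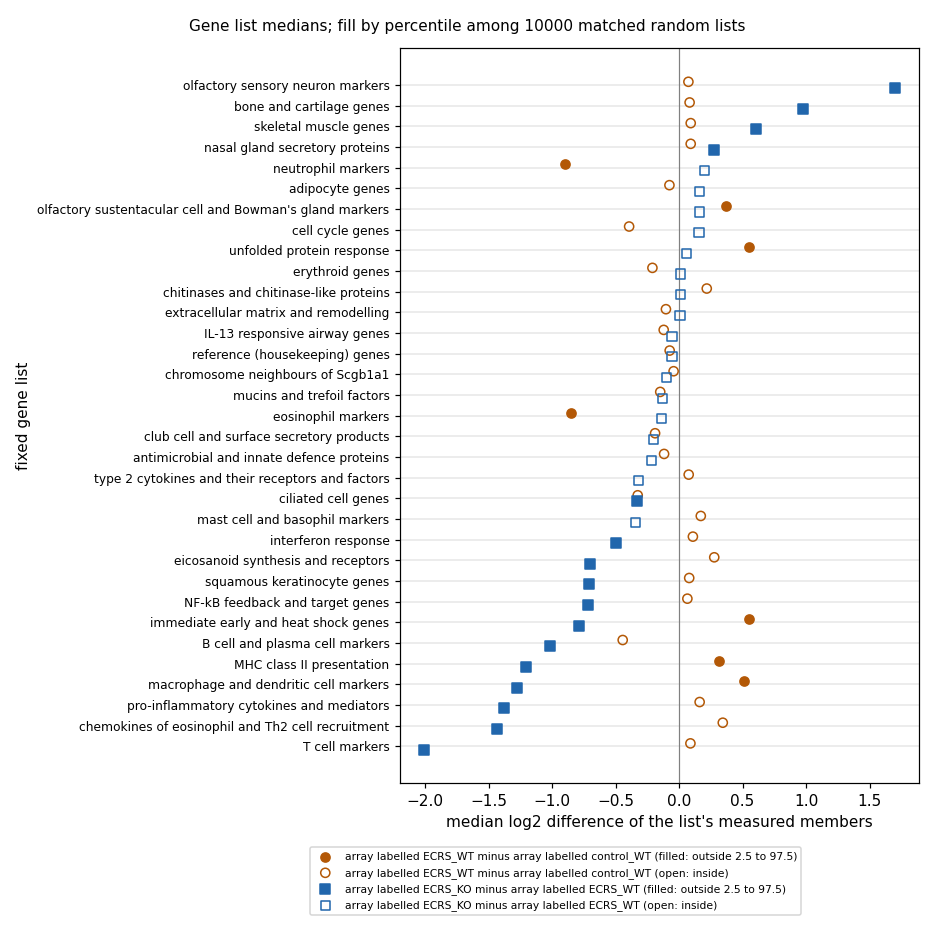
Median log2 difference (horizontal axis) of each fixed gene list (vertical axis) for the array labelled ECRS_WT minus that labelled control_WT (circles) and the array labelled ECRS_KO minus that labelled ECRS_WT (squares); symbols are filled where the median lay outside percentiles 2.5 to 97.5 of 10000 matched random lists. Olfactory sensory neuron markers (1.70) and bone and cartilage genes (0.98) were highest, and T cell markers (-2.01) lowest, on the array labelled ECRS_KO.

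The comparison of ECRS_KO with ECRS_WT asked how loss of CC10 altered expression in diseased mucosa. On the array labelled ECRS_KO, where Scgb1a1 itself was detected, 4 of 4 measured T cell markers, 6 of 8 macrophage and dendritic cell markers, 6 of 9 MHC class II genes and 4 of 5 chemokines were at least 2-fold lower, and 12 of 14 olfactory sensory neuron markers and 5 of 10 bone and cartilage genes at least 2-fold higher. Cd3d and Cd3e of the T cell receptor complex were 4.41-fold and 4.26-fold lower, and Chil4, a chitinase-like protein of allergic airways, was 5.35-fold lower. Cnga2, the olfactory cyclic nucleotide-gated channel, was 3.96-fold higher and Col2a1, the collagen of cartilage, 3.93-fold higher. Altogether 421 genes were at least 2-fold higher and 210 at least 2-fold lower among 8917 genes detected on either array, and 92.9% lay within 2-fold.

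The highest differences among genes detected on both arrays were nearly all in olfactory receptor genes, each used by a small share of olfactory neurons. Olfr424 was 5.92-fold higher, Olfr655 5.85-fold, Olfr969 5.69-fold, Olfr1019 5.55-fold and Olfr247 5.51-fold. Olfr615 followed at 5.45-fold, Olfr690 at 5.30-fold, Rtp2 also at 5.30-fold, Olfr1511 at 5.11-fold and Olfr635 at 4.81-fold. Of genes not detected on the array labelled ECRS_WT, Bpifb9b was at least 20.6-fold higher, Olfr651 at least 7.90-fold and Tafa4, a secreted neuronal protein, at least 7.23-fold. Signals of Bpifb9b were 1146, -14.1 and 891 on the arrays labelled control_WT, ECRS_WT and ECRS_KO, so that it went undetected on the array labelled ECRS_WT only.

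The lowest gene detected on both arrays was Gp2, a glycoprotein of secretory granules and of M cells, 6.50-fold lower on the array labelled ECRS_KO. Chil4 came next, and then the chemokine gene Ccl8 at 5.15-fold and Cfi, complement factor I, at 5.07-fold. Tmem108 was 4.92-fold lower and Csrnp1, a nuclear protein of immediate early type, 4.61-fold. Cxcl9, an interferon-induced chemokine, was 4.2-fold lower and Slpi, an inhibitor of leukocyte proteases, 4.01-fold. Among genes not detected on the array labelled ECRS_KO, Gpnmb, a glycoprotein of macrophages and melanocytes, was at least 20.3-fold lower. Mmp3 was at least 11.7-fold lower and Mlana, a melanosome protein, at least 5.38-fold lower. Of 3 measured melanocyte genes, a family also chosen after its values were seen, 2 were lower, namely Gpnmb and Mlana. The family median was -2.43 at percentile 0 (-0.25 under limma's own inference). Both genes were already among the 3 lowest just named, so this percentile is no separate result.

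All 4 measured T cell markers, of 12 with a probe, were at least 2-fold lower on the array labelled ECRS_KO. Their median log2 difference was -2.01 at percentile 0 (-0.71 under limma's own inference). It depended on the members that were detected, being -1.14 at a detection p under 0.05 and -0.75 without a detection filter. Cd3g was 3.80-fold lower. Of 8 macrophage and dendritic cell markers 6 were lower and none higher (median -1.27, percentile 0), with the complement genes C1qb and C1qc 3.41-fold and 2.90-fold lower and Ms4a7 2.86-fold. Of 9 MHC class II presentation genes 6 were lower and none higher (median -1.21, percentile 0). H2-Aa was 3.77-fold lower, H2-Eb1 2.80-fold, and Cd74, the invariant chain, 2.64-fold with signals of 5978 on the array labelled ECRS_WT and 2911 on the array labelled ECRS_KO. Of 5 B cell and plasma cell markers 3 were lower (median -1.01, percentile 0, and -0.14 under limma's own inference), namely Tnfrsf17, a receptor of plasma cells, by 2.98-fold, Mzb1 by 2.62-fold and Pou2af1 by 2.02-fold.

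Chemokines of eosinophil and Th2 cell recruitment were lower in 4 of 5 measured members (median -1.44, percentile 0), with Ccl5 at least 3.37-fold and Ccl7 2.70-fold lower beside Ccl8. Pro-inflammatory cytokines and mediators were lower in 4 of 5 (median -1.38, percentile 0), with Ccl4 at least 4.0-fold, Cxcl1 3.82-fold and Il1b, which encodes interleukin-1 beta, 2.60-fold lower. The adhesion molecule gene Icam1 was 2.33-fold lower and Bcl3 at least 2.39-fold lower among 6 NF-kB feedback and target genes (median -0.71, percentile 0.04). Ptges, a prostaglandin E synthase, was 2.25-fold lower among 9 eicosanoid genes (median -0.70, percentile 0.04). Interferon response genes had a median of -0.50 at percentile 2.30, with Cxcl9 the 1 member at least 2-fold apart. Under limma's own inference the medians of these lists were closer to 0, at -0.14 for the chemokines, -0.22 for pro-inflammatory mediators, -0.07 for NF-kB genes, -0.05 for eicosanoid genes and -0.05 for interferon response genes. The 7 measured immediate early and heat shock genes had a median of -0.79 at percentile 0.02 and none was 2-fold apart; Dusp1 was 1.14-fold and Ier3 1.91-fold lower.

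Other leukocyte and type 2 lists differed less on the array labelled ECRS_KO. Prg2, the 1 measured eosinophil marker, was 1.10-fold lower (0.06 log2 higher under median scaling), with signals of 886 on the array labelled ECRS_WT and 1106 on the array labelled ECRS_KO before normalization. Neutrophil markers had a median of 0.20 at percentile 96.8, with S100a8 1.02-fold and Camp 1.04-fold lower. The mast cell protease genes Cma1 and Mcpt4 were each lower, by 2.35-fold and 2.35-fold, in a list with a median of -0.34 at percentile 6.76. Type 2 cytokines, receptors and factors had a median of -0.32 at percentile 8.61, with the epithelial alarmin gene Il33 1.34-fold higher and Il13ra1 1.25-fold lower. Among interleukin-13 responsive genes (median -0.06, percentile 44.7, positive under median scaling) Itln1 was 2.79-fold and Serpinb2 2.37-fold lower. Of 5 chitinases and chitinase-like proteins 2 were lower, Chil4 and Chil1 (2.26-fold), while the list median was 0.01 at percentile 61.7 and negative with the mean of probes.

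Of 14 measured olfactory sensory neuron markers 12 were at least 2-fold higher on the array labelled ECRS_KO and none lower, with a median of 1.70 at percentile 100. Gnal, the olfactory G protein subunit, was 4.54-fold higher. Of 997 olfactory receptor genes with a probe, a family chosen after its values were seen, 289 were measured, 122 were at least 2-fold higher and none lower (median 0.85, percentile 100), whereas under limma's own inference 4 were higher and the median was 0.06. Of 8 sustentacular cell and Bowman's gland markers 1 was higher, Umodl1 by 2.84-fold, and the median was 0.16 at percentile 93.8 (-0.03 after scaling on probes detected on all arrays). Of 9 nasal gland secretory proteins 4 were higher and 1 lower (median 0.28, percentile 99.0, and -0.18 after scaling on probes detected on all arrays), with Pip, the prolactin-induced protein, 3.24-fold and Lcn4, a lipocalin, 2.46-fold higher. Bone and cartilage genes were higher in 5 of 10 measured members (median 0.98, percentile 99.99), with the cartilage matrix genes Comp and Acan 2.40-fold and 2.31-fold higher. Of 5 skeletal muscle genes 1 was higher, the calcium pump gene Atp2a1 by 2.26-fold (median 0.61, percentile 98.6, but negative with probes detected on all 3 arrays or without a detection filter, and 0.04 under limma's own inference, where Atp2a1 was 0.11 log2 higher), and the globin gene Hbb-b2 was 2.19-fold higher among erythroid genes (median 0.01, percentile 61.3).

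Secretory and barrier genes of the epithelium were lower in part on the array labelled ECRS_KO. Slpi, Lcn2, an iron-sequestering defence protein (3.44-fold), and Pigr, the transporter of mucosal antibodies (2.05-fold), were lower among 8 antimicrobial and innate defence proteins (median -0.22, percentile 6.52). The mucin genes Muc4, Muc1 and Muc20 were 2.55-fold, 2.35-fold and 2.04-fold lower among 8 mucins and trefoil factors (median -0.13, percentile 25.3). Bpifb1 was 2.16-fold lower among 10 other club cell and surface secretory products (median -0.20, percentile 4.2). Sprr3 and Sprr1a, precursors of the cornified envelope, were at least 4.22-fold and 2.48-fold lower among squamous keratinocyte genes (median -0.71, percentile 0.01, and -0.17 under limma's own inference). Ciliated cell genes had a median of -0.33 at percentile 1.5 with none 2-fold apart, Rsph1 being 1.13-fold and Tekt1 1.04-fold lower.

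The remaining lists lay inside the range of most random lists. Medians, of which those of matrix and adipocyte genes changed sign without a detection filter and that of cell cycle genes with probes detected on all 3 arrays, were 0.01 (percentile 59.1) for extracellular matrix genes, with Mmp2 1.34-fold lower and Ccn2 1.47-fold higher, 0.16 (percentile 80.4) for adipocyte genes, with Cidea 1.12-fold higher and Adipoq 1.22-fold lower, and 0.16 (percentile 76.8) for cell cycle genes, with Mcm5 1.26-fold higher and Birc5 1.02-fold lower. Genes of the unfolded protein response had a median of 0.06 (percentile 75.6), with Xbp1 1.12-fold lower and Herpud1 1.08-fold higher, and reference genes one of -0.06 (percentile 40.7, positive at a detection p of 0.05), with Ppia 1.06-fold higher and Actb 1.20-fold lower. The 22 measured neighbours of Scgb1a1 all lay within 2-fold (median -0.10, percentile 23.4, positive under median scaling), Fth1 being 1.19-fold and Eef1g 1.12-fold lower. Cytosolic ribosomal protein genes had a median of -0.10 at percentile 7.88.

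In the genotype comparison, median scaling gave 562 genes higher and 126 lower, with 81.7% of the genes apart being higher against 66.7% under quantile normalization and a median of all genes of 0.13 against -0.05. Limma's own inference of the background gave 143 and 81, of which 120 and 54 genes were shared, and 26 of the 67 named genes at 2-fold or more kept that size. Of the genes named for the largest differences, Olfr969, Olfr615, Rtp2, Bpifb9b, Chil4, Slpi and Gpnmb kept 2-fold there, and the others, Cd3d (-0.79 log2), Cd3e (-0.65), Gp2 (-0.83) and Ccl8 (-0.53) among them, did not. List medians there were 1.41 for olfactory sensory neuron, 0.70 for bone and cartilage, 0.14 for nasal gland, -0.96 for macrophage, -0.82 for MHC class II, -0.47 for immediate early and heat shock, -0.14 for ciliated cell and -0.04 for type 2 genes.

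Between the arrays labelled ECRS_KO and control_WT, which differ by label in both disease and genotype, 626 genes were at least 2-fold higher and 515 lower on the former among 9086 genes detected on either. The percentage of these genes that were higher was 54.9% under quantile normalization, 90.8% under median scaling and 44.1% after scaling on probes detected on all arrays, where the medians of all genes were -0.13, 0.24 and -0.21. Limma's own inference gave 211 genes higher and 148 lower. Of genes already named, Rtp2 was at least 35.3-fold higher and Stoml3 9.34-fold higher on the array labelled ECRS_KO, while Cd3d was 5.18-fold lower and Ccl8 4.0-fold lower.

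Of the 328 genes higher on the array labelled ECRS_WT than on the array labelled control_WT, 15 were at least 2-fold lower and 13 at least 2-fold higher on the array labelled ECRS_KO than on the array labelled ECRS_WT. Of the 125 lower genes, 22 were higher and 2 lower in the second comparison. Mmp3, C1qc, Ms4a7, Muc1 and Cxcl1 were among the former 15, and Pip and Bpifb9b among the latter 22. The differences had opposite signs for 61.6% of the 453 genes. Because both comparisons share the array labelled ECRS_WT, opposite signs arise without any effect: 100 simulations of unchanged arrays gave 95.5% (86.8% to 100%) of 49.8 genes on average. Independent lists of these sizes would share 8.18 genes higher then lower, 6.25 lower then higher, 16.4 higher in both and 3.12 lower in both. Across the 7059 genes detected on all arrays, which are not independent replicates, the covariance of the differences was -0.0292 against -0.0611 in the simulations, a gap of 0.0318. The simulated noise was taken from the observed differences between the arrays labelled ECRS_KO and ECRS_WT, which also hold any genotype effect. The simulations thus show the direction of the bias and give no baseline for the 61.6% or for this gap. Under median scaling 42.6% of the genes had opposite signs.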

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

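Of the tests in this part, that on the neighbours of Scgb1a1 was written before its result was seen and all others were chosen after. A gene stood apart on 1 array when it was at least 2-fold from both other arrays in the same direction. The other 2 arrays had to lie within 1.5-fold of each other.

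Signals were also found in probes without a single gene symbol, which no comparison used. Of 3461 detected ones, 271 were at least 2-fold higher and 42 lower on the array labelled ECRS_WT than on the array labelled control_WT, and of 3711, 368 were higher and 148 lower on the array labelled ECRS_KO. These numbers were 345 and 13, and 713 and 46, under median scaling, and 68 and 10, and 96 and 41, under limma's own inference.

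Scgb1a1 was not detected on the array labelled control_WT and was detected on the array labelled ECRS_KO, which rests on the deposited detection p-values and not on the background inference. Fewer club cells in the pool labelled control_WT were not seen in the other club cell and surface secretory products. Their median differed by -0.19 between the arrays labelled ECRS_WT and control_WT, and all 10 lay within 2-fold. Members such as Cbr2, also listed as a sustentacular and gland marker, may come from other cells. This median therefore cannot exclude fewer club cells. An exchange of the labels control_WT and ECRS_KO may explain the pattern: around Scgb1a1, 5 of 178 genes (2.81%, exact interval 0.918% to 6.43%) stood apart on the array labelled control_WT, against 2.70% of 9052 others (two-sided Fisher exact p 0.815), so no excess was seen. The bound written beforehand took this as evidence against an exchange, which was too strict, since the labels give every mouse as C57BL/6 and an exchange then needs no passenger difference, and the interval is wide. Between the arrays labelled ECRS_KO and control_WT, medians were below 0 in 10 of 10 immune lists. These were eosinophil, mast cell and basophil, T cell, B cell, macrophage, neutrophil, MHC class II, interferon, chemokine and pro-inflammatory genes. The median of mast cell and basophil genes was -0.01 only, and 0.37 under median scaling. That of type 2 cytokines, not among these lists, was 0.01. An exchange, which would set diseased mice under the label control_WT, could give lower levels under the label ECRS_KO. An effect of the knockout, whose direction is not known here, could give them too, so these medians do not tell the 2 apart. A probe outside the deleted part also stays open for the signal on the array labelled ECRS_KO. It would not account for the lack of signal on the array labelled control_WT.

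On the array labelled ECRS_KO, the median of olfactory sensory neuron markers was higher and those of T cell and most other immune lists lower than on the array labelled ECRS_WT. The neuron median exceeded the T cell median by at least 2.12 (log2) under the settings of background, detection, probes and arrays run on lists. A scaling of whole arrays cancels from this gap, but under both scalings the medians kept opposite signs (1.72 and -1.76, 1.54 and -1.95). The pattern of these 2 lists thus outlasted the choice of processing. They were the fixed lists with the highest and lowest medians, and the test was chosen after these were seen. Every setting also reprocessed the same arrays, so a fault of an array, such as its brightness, cannot be excluded by this gap. A larger share of olfactory mucosa as a whole would raise neuron markers and sustentacular and gland markers alike. The neuron median was higher by 1.54 (combined bootstrap SD 0.37 over list members), so the 2 lists did not rise equally. Some sustentacular and gland markers are expressed by other cells too. Of these markers, Cyp2g1 and Umodl1 were higher by 0.76 and 1.5 (log2), while 3 of 8 were below 0. A larger share of olfactory mucosa therefore stays open. A different share of neurons in the pool and the genotype may remain too, and neither was tested.

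On the array labelled control_WT alone, 252 genes stood apart, 198 of them lower there. Other probes of these genes, 23 in number, had a median difference of 0.26 in the direction of the gene's own probe, against 1.65 for the own probes, and 8 of them reached 2-fold; for the array labelled ECRS_KO these medians were 0.84 and 1.36. The own probes were selected at 2-fold or more and had the highest mean signal of their genes, on either array's list. Smaller differences of the other probes can arise from that selection. Effects on single probes, such as variants under a probe or faulty probes, remain a candidate explanation for part of these genes, which these medians cannot decide. Disease, which the labels also set against control_WT, was not tested separately.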

How the results depend on the processing

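Limma's own inference, scaling on probes detected on all arrays and normalization without the third array were chosen after seeing the data. Counts are given as higher and lower genes for ECRS_WT against control_WT, ECRS_KO against ECRS_WT and ECRS_KO against control_WT; the cause was not tested unless stated.

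Median scaling gave 511 and 43 in the first comparison, 126 lower in the second and 1272 and 129 in the last, with 42.6% of genes of opposite sign. Without background correction there were 201 and 41, then 124 lower, then 254 lower; with an offset of 50 there were 201 and 42, then 121 lower, then 250 lower. The authors' values gave 128 and 42, 212 and 95, and 293 and 221. Probes detected on all 3 arrays gave 213 and 80, then 250 higher, then 383 higher, since fewer genes were counted. At 1.5-fold there were 857 and 952, 851 and 783, and 1354 and 1788, and at 3-fold 99 and 13, 141 and 39, and 230 and 66, by construction. Limma's own inference gave 108 and 41, 143 and 81, and 211 and 148. Other counts under these settings, and all counts under detection p 0.05, no detection filter, the mean of probes, scaling on probes detected on all arrays and normalization without the third array, lay within 1.5 times those reported.

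Between ECRS_KO and ECRS_WT the skeletal muscle median of 0.61 was -0.0091 with probes detected on all 3 arrays and -0.036 without a detection filter, and the nasal gland median of 0.28 was -0.18 after scaling on probes detected on all arrays; the cause was not tested. Of 102 list medians, 35 moved by more than their bootstrap SD under limma's own inference, 34 under median scaling, 23 without a detection filter, 20 with the authors' values and 20 after scaling on probes detected on all arrays. The reversed medians given above were counted apart from these. Under limma's own inference, T cell markers went from -2.01 to -0.71 between ECRS_KO and ECRS_WT, and Scgb1a1 from 3.84 to 0.86 between ECRS_WT and control_WT. Of 167 values of named genes, 95 moved by more than the SD between probes of a gene under limma's own inference and 66 with the authors' values. Of named genes at 2-fold or more, 20 of 54 and 26 of 67 kept that size under limma's own inference in the first and second comparisons, 40 and 52 with the authors' values, 44 and 58 without background correction, and 48 and 60 under median scaling. Ccl5 went from -1.75 to -0.14, Olfr424 from 2.57 to 0.58, Fos from 1.26 to 0.39 and Hspa1a from 1.32 to 0.09 under limma's own inference. None of the named genes at 2-fold or more changed sign under the alternatives run on single genes. Signal over background limits the folds: 113 of 328 higher and 41 of 125 lower genes in the first comparison, and 135 of 421 and 49 of 210 in the second, are lower bounds. No paired analysis was possible because each group had 1 array.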
